A study of Mus musculus with 2 samples.

How the data were processed

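Small RNA from the hearts of 2 male B6CASTF1/J mice, 10 days old, was sequenced as 1 library per animal, and the labels give the libraries biological replicate numbers 1 and 2. The labels state total RNA as the starting material and an upper limit on fragment size. Both libraries formed 1 group, so no contrast between groups was computed and no p-value concerns a condition. The labels also give both samples a common donor identifier beside separate sample identifiers, and the samples were treated as separate animals on the strength of the latter.

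The authors deposited raw read counts per microRNA gene, 1 table per library, with no normalization. The genome build was mm10 and the annotation was GENCODE M21, per the deposited text that accompanies the tables. The aligner, the counting program and their settings are not given in the sources used here. Each table holds 3 columns of counts for 2202 genes and no header. The column meanings were inferred from the values: reads on both strands, reads on the strand of the gene and reads on the opposite strand. The column for the gene strand was used. The column for both strands gives no count to most reads of genes that overlap a gene on the other strand, which is the behaviour of a count that drops ambiguous reads. A further 4 entries in each table name no gene and stayed out of library sizes and tests. Reads with several mapping positions were 36.8% of all reads in replicate 1 and 48.1% in replicate 2, unmapped reads 16.0% and 11.5%, and reads outside the genes 4.78% and 3.43%. Reads on the gene strand made up 42.4% and 37.0%. Reads with several mapping positions were in none of the gene counts, and how the counting treated microRNAs encoded in several copies is not given in the sources used here.

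All 2202 identifiers were found in the GENCODE M21 annotation, which supplied coordinates, strand and host genes, and hairpin sequences came from the mm10 genome. Another 5 annotated microRNA genes on unplaced scaffolds were not used here. Counts were scaled to a library total of 1000000 over the microRNA genes and are given as CPM. The totals were 3748432 in replicate 1 and 6305782 in replicate 2. Genes with at least 10 counts in both libraries were called detected (340 genes). A gene was marked as sharing sequence where its hairpin holds a stretch of 20 bases found in another counted hairpin. Intervals of shares and ratios are exact Clopper-Pearson 95% intervals, and the lower limit of detection was set at 3 counts.

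The replicates were compared by Pearson and Spearman correlation of log2(CPM + 1) and by the common dispersion of edgeR 4.0.16 with an intercept-only design and TMM scaling. The counts of each detected gene in the 2 libraries were set against the ratio of TMM-scaled library sizes with an exact two-sided binomial test, adjusted by Benjamini-Hochberg at 0.05. The log2 ratio of replicate 2 over replicate 1 used a prior of 0.5 counts. Gene lists for cell types, families and clusters, 20 in all, were fixed before the data were examined, and all 161 list entries were matched, 3 of them through a synonym. The calls adjusted over the list alone matched those over all genes in number for every list but that of miR-17-92 and its paralogous clusters, with 10 against 9. The median log2 ratio of each list with at least 3 detected genes was placed among 10000 random lists of the same size. For each member, the draw was from that member and the 40 genes nearest to it in mean level, so a random list could hold genes of the list itself.

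Genes were named by a rule fixed before the data were examined. It takes the 20 genes with the highest mean CPM, every cardiac muscle gene and the 2 most abundant detected genes of each other list, or the top gene where none was detected. It adds the 5 genes with the largest difference between the libraries in each direction among those that passed the test with a mean of at least 10 CPM, and both genes of 6 ratios. The rule gave 65 genes.

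The procedure was tested on simulated counts drawn from these libraries. For the calls, the counts were Poisson draws around the pooled profile of both libraries and so held counting error only. Over 335 simulated genes the procedure called 74.0% of genes changed by a log2 value of 0.5 and 89.7% of those changed by a log2 value of 1. It also called 13.4% of unchanged genes, since TMM misplaced the zero by 0.03 on the log2 scale and the counts were high, against 2.82% with the true scaling and 0 at a difference of at least 2-fold. The count of 245 genes is to be read with that in mind, and small ratios are less secure against a misplaced zero than those of 2-fold or more. Spread between libraries beyond counting error was not simulated for the calls, so neither the 13.4% nor the 0 at 2-fold covers it. In the real libraries the scalings parted from TMM by more than 0.03, by 0.08 for DESeq2 size factors and 0.14 for total counts. The 13.4% may therefore be too low for the 245 genes. Simulated coefficients of variation of 0.2 and 0.6 were estimated as 0.194 and 0.579.

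Alternatives fixed before the data were examined were the strand column, the count minimum, the scaling (TMM, DESeq2 1.42.0 size factors or total counts), the pseudocount, the denominator and leaving out each replicate. Tests and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3. Mature arms and isoforms could not be separated in counts per gene.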

Results

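MicroRNA sequencing of heart tissue from male B6CASTF1/J mice gave 2 libraries of total RNA selected for short fragments. B6CASTF1/J is the hybrid offspring of the C57BL/6J laboratory strain and the CAST strain, which derives from wild mice. The animals were 10 days old, an age at which the mouse heart is still maturing after birth. The labels name a separate biological sample for each library, so the libraries were treated as biological replicates 1 and 2 of 1 group. No other tissue, age or strain was part of the series analysed here, and the design therefore implies a description of the heart microRNAs and a comparison of the replicates. The count on the gene strand over 2202 microRNA genes was 3748432 in replicate 1 and 6305782 in replicate 2. At these depths 3 counts, the upper limit that a count of 0 allows, equalled 0.8003 CPM (counts scaled to a library total of 1000000) in replicate 1 and 0.476 CPM in replicate 2. Intervals and limits from counts cover counting error only, because amplified reads are not independent molecules. CPM values are without TMM scaling, whereas folds and log2 ratios between the libraries were computed after it and so differ by 0.14 on the log2 scale from the ratio of the CPM values. All SDs below are over the 2 replicates (n = 2).

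Among reads assigned to a microRNA gene, the heart libraries were led by Mir378a, by members of the let-7 family and by the endothelial microRNA Mir126a. Reads with several mapping positions, 36.8% of all reads in replicate 1 and 48.1% in replicate 2, were outside these counts. All ranks and shares below therefore hold for the assigned reads only and may not give the order in the tissue. In all, 340 genes had at least 10 counts in both libraries and are called detected here, and 1469 genes had no count in either. Mir378a took 13.8% ± 0.0641 of all counts, the 10 genes with the highest mean CPM took 64.2% ± 2.17, and the 20 with the highest mean took 80.0% ± 1.05. Of the 20 most abundant genes of each library, 17 were shared. Mir378a (ENSMUSG00000105200.1; chromosome 18, 61397835 to 61397900, minus strand, mm10) lies in an intron of Ppargc1b, which encodes a coactivator of mitochondrial genes, and its mean was 138304 ± 641 CPM. Its hairpin shares at least 20 bases with another counted hairpin, so its level is uncertain where reads fit both.

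Mirlet7i followed at 95859 ± 20442 CPM and Mirlet7g, in an intron of Wdr82, at 69882 ± 4269 CPM. Mirlet7d (34196 ± 12567 CPM) and Mirlet7b (25900 ± 4299 CPM) were also among the 20 leading genes. The let-7 microRNAs are a large family linked to developmental timing and differentiation. Mir126a, within the endothelial gene Egfl7 (chromosome 2, 26591357 to 26591429, plus strand), reached 94759 ± 8207 CPM. Mir99a (51092 ± 4416 CPM), Mir23b (47721 ± 4937 CPM), Mir143 (47486 ± 5525 CPM) and Mir23a (37164 ± 6264 CPM) came next, and the hairpins of Mir23b and Mir23a each share at least 20 bases with another counted hairpin.

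Below these lay Mir30d at 21876 ± 1364 CPM, Mir322 at 19589 ± 5834 CPM and Mir99b at 18811 ± 8830 CPM. Mir335, in an intron of the imprinted gene Mest, had 16103 ± 5533 CPM, and Mir139 had 13608 ± 527 CPM. Mir30a had 12488 ± 4090 CPM and Mir652 had 10240 ± 3360 CPM. Mir30e had 6516 CPM in replicate 1 and 13611 CPM in replicate 2, and Mir130a had 5371 and 13314 CPM. Mir26b, in an intron of Ctdsp1, was the least even of the 20 leading genes. It had 12906 CPM in replicate 1 and 37666 CPM in replicate 2, a 3.22-fold difference after TMM scaling.

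**Figure D1:**
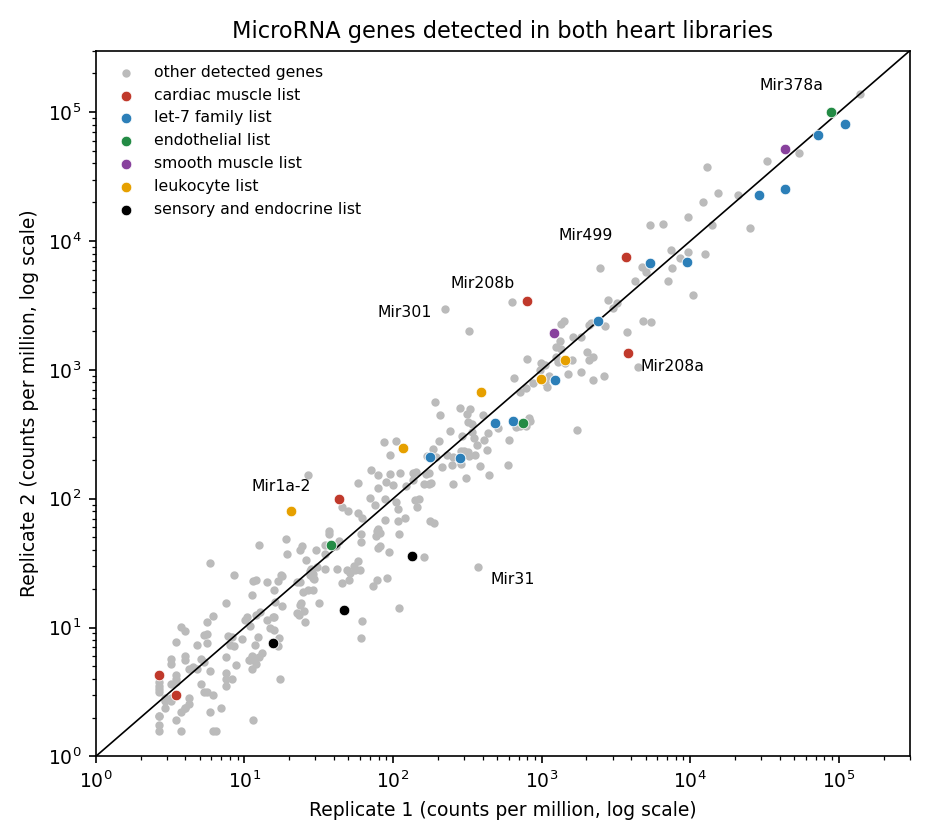
Each point is 1 of the 340 microRNA genes with at least 10 counts in both heart libraries, with CPM in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis, both on log scales. The line marks equal values; Mir208a lies below it, Mir208b and Mir301 lie above it, and Mir31 lies far below it.

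Among the 7 genes of the cardiac muscle list, the 3 that sit inside myosin genes held most of the counts. Mir499, in an intron of the myosin gene Myh7b (chromosome 2, 155622880 to 155622958, plus strand), had 3678 CPM in replicate 1 and 7542 CPM in replicate 2. Mir208a had 3795 and 1362 CPM, and Mir208b had 794 and 3444 CPM. Mir1a-2 had 43.2 and 99.6 CPM. The list as a whole took 0.832% of the counts in replicate 1 (exact binomial 95% interval 0.823% to 0.841%) and 1.25% in replicate 2 (1.24% to 1.25%). These shares leave out reads with several mapping positions, and 4 of the 7 genes share at least 20 bases with another counted hairpin. They may therefore understate the list. Of the 6 detected members of the list, 3 were higher in replicate 2 (Mir499, Mir208b and Mir1a-2), 1 was lower (Mir208a) and 2 did not pass the test, under each of the 3 scalings tried.

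The genes of miR-1 and miR-133a, known as the abundant microRNAs of striated muscle, held few counts. Mir1a-1 had 13 counts in replicate 1 and 19 in replicate 2, Mir133a-1 had 10 and 27, and Mir133a-2 had 2 and 4. All 4 of these hairpins share at least 20 bases with another counted hairpin. Reads with several mapping positions were outside the gene counts and made up 36.8% of all reads in replicate 1 and 48.1% in replicate 2. The level of miR-1 and miR-133a in the tissue is therefore uncertain. Within these limits, Mir1a-1 to Mir1a-2 had a log2 ratio of -4.30 ± 1.00 and Mir133a-1 to Mir133a-2 one of 2.34 ± 0.38. The exact 95% interval of the Mir133a-1 share in replicate 1 ran from 51.6% to 97.9%.

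**Figure D2:**
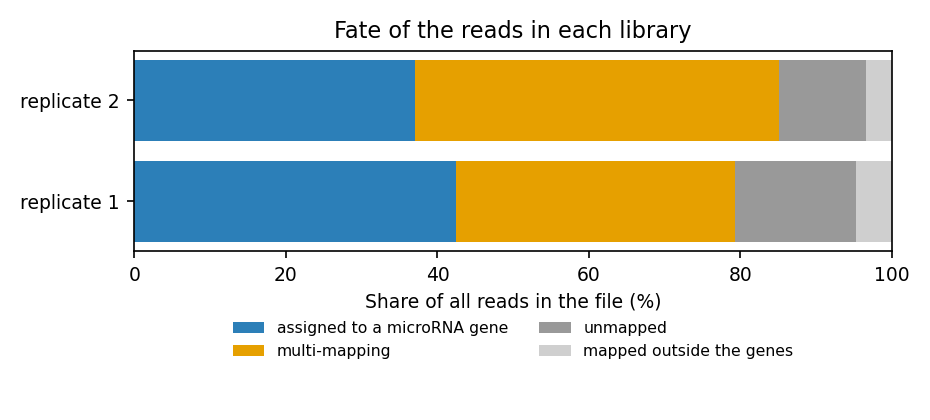
The bars split all reads of each heart library into those assigned to a microRNA gene, those with several mapping positions, those that did not map and those that mapped outside the genes, as percent of all reads on an axis that starts at 0. Reads assigned to a gene were 42.4% in replicate 1 and 37.0% in replicate 2.

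Mir208a and Mir208b differed between the libraries in opposite directions. Mir208a lies in an intron of Myh6 (chromosome 14, 54949060 to 54949142, minus strand), which encodes the alpha myosin heavy chain that prevails in the adult mouse ventricle. Mir208b lies in an intron of the neighbouring Myh7 (chromosome 14, 54975700 to 54975776, minus strand), which encodes the beta chain that prevails before birth. After TMM scaling Mir208a was 2.52-fold lower in replicate 2 than in replicate 1 (log2 ratio -1.34, exact 95% interval -1.37 to -1.30). Mir208b was 4.78-fold higher (log2 ratio 2.26, interval 2.20 to 2.31). Of the counts of this pair, Mir208a took 82.7% in replicate 1 (exact 95% interval 82.1% to 83.3%) and 28.3% in replicate 2 (27.8% to 28.9%). The pair therefore has no common direction over the replicates, and its mean log2 ratio of 0.46 ± 2.54 describes neither library.

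Endothelial and smooth muscle microRNAs were abundant in both libraries. The endothelial list took 8.97% of the counts in replicate 1 and 10.1% in replicate 2, nearly all from Mir126a. Mir221 had 566 ± 252 CPM and was lower in replicate 2 (log2 ratio -0.80). Of the 3 detected members, 2 were higher in replicate 2 and 1 lower, and with total counts as the scaling 1 was higher and 1 lower. The smooth muscle list took 4.48% and 5.33%, and both of its genes, Mir143 and Mir145a, were higher in replicate 2 by log2 ratios of 0.38 and 0.81. Mir143 exceeded its cluster partner Mir145a in each library, with a mean log2 ratio of 4.96 ± 0.30.

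Blood and mesenchymal microRNAs took smaller shares. The erythroid list took 1.02% in replicate 1 and 0.886% in replicate 2. Its leading gene was Mir451a, a product of red cell precursors, at 8921 ± 948 CPM, and its partner Mir144 had 385 ± 96.5 CPM. Of its 4 genes 1 was higher in replicate 2 and 2 lower, and with DESeq2 size factors Mir451a lost its call. The log2 ratio of Mir451a to Mir144 was 4.55 ± 0.52. The leukocyte list took 0.295% and 0.304%, led by Mir155 (1310 ± 169 CPM) and Mir146 (917 ± 100.1 CPM), whose hairpin shares at least 20 bases with another and whose level is uncertain for that reason. The 3 less abundant detected genes of that list were higher in replicate 2 under each of the 3 scalings. Mir155 and Mir146 were lower, by log2 ratios of -0.12 and -0.08, but lost that call with DESeq2 size factors. The fibroblast and mesenchymal list took 0.393% and 0.794%. Of its 5 genes, 3 share at least 20 bases with another counted hairpin, so these shares are uncertain. Mir21a, often raised in activated fibroblasts, had 2474 CPM in replicate 1 and 6146 CPM in replicate 2, and Mir214 had 1505 ± 244 CPM. Of the 4 detected genes of that list, 3 were higher in replicate 2 and 1 lower, and with DESeq2 size factors the lower one lost its call. Mir199a-1 had 1 and 2 counts, below the limit of 3 counts, and shares sequence with Mir199a-2. Their log2 ratio of -6.07 ± 0.67 is uncertain for both reasons, and the exact 95% interval of the Mir199a-1 share in replicate 1 ran from 0.0347% to 7.40%.

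Among the family lists, let-7 took the largest share, 27.5% of the counts in replicate 1 and 21.5% in replicate 2. All 12 of its genes were detected, and 8 were lower and 4 higher in replicate 2. With total counts as the scaling 9 were lower and 2 higher, and Mirlet7g turned from higher (log2 ratio 0.02) to lower (-0.12). The miR-30 family took 3.81% and 5.27%, with 4 of 6 genes higher in replicate 2 under each of the 3 scalings and 2 lower, or 1 lower with DESeq2 size factors. Mir30e was higher by a log2 ratio of 1.21 and Mir30a by 0.82. The miR-15/16 family, linked to cell cycle control, took 0.593% and 0.902%. Of its 6 genes 4 were higher in replicate 2 and 1 lower, against 5 and 1 with DESeq2 size factors and 4 and 2 with total counts. Mir195a had 634 and 3377 CPM, and Mir16-1, which shares sequence with another hairpin, had 1423 and 2410 CPM. The miR-29 family took 0.0336% and 0.0275%, led by Mir29a (266 ± 44.97 CPM) and Mir29c (30.3 ± 0.913 CPM), the latter uncertain because its hairpin shares sequence with another. Only Mir29a of that family passed the test, with a log2 ratio of -0.20. Genes that share at least 20 bases with another counted hairpin were 6 of 12 in let-7 and 3 of 4 in the miR-29 family. They were 2 of 6 in the miR-30 family and 2 of 6 in the miR-15/16 family. The shares of these 4 lists are uncertain for that reason.

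Clustered microRNAs of growth and imprinting were present at intermediate levels. The list of miR-17-92 and its paralogous clusters, tied to cell proliferation, took 1.43% and 1.63%. Mir93 had 5395 ± 538 CPM and Mir17 had 4568 ± 415 CPM. Of the 11 detected genes of that list, 7 were higher in replicate 2 and 2 lower, with 6 and 2 under total counts and 8 and 2 under DESeq2 size factors. The list of the X-linked cluster of Mir322 and its neighbours took 2.75% and 2.91%. Its leading genes differed in opposite directions, Mir322 by a log2 ratio of 0.76 and Mir351 by -1.31. The Dlk1-Dio3 list, from an imprinted region of chromosome 12 expressed from the maternal copy, took 1.66% and 1.18%. Of its 44 detected genes 14 were higher in replicate 2 and 22 lower, against 14 and 20 with DESeq2 size factors and 12 and 24 with total counts. Mir127 of that region had 3596 ± 1686 CPM and was lower in replicate 2 (log2 ratio -0.85), and Mir379 had 3015 ± 21.7 CPM. The Hox-embedded list took 0.235% and 0.237%, led by Mir10a (1378 ± 193 CPM) and Mir10b (929 ± 171 CPM).

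MicroRNAs known from other tissues lay low. The epithelial list took 0.0476% in replicate 1 and 0.0546% in replicate 2, led by Mir200c at 423 ± 27.7 CPM, and Mir200b had 12.5 and 43.5 CPM. Of the 6 epithelial genes 3 were higher in replicate 2 and 1 lower, and the lower one lost its call with DESeq2 size factors. The sensory and endocrine list took 0.0197% and 0.00577%, with Mir182 at 134 and 36.2 CPM and Mir183 at 47.0 and 13.6 CPM. Mir122, the leading microRNA of hepatocytes, had 57.9 and 77.7 CPM. The skeletal muscle list took 0.00285% and 0.00211%, and its Mir206 had 23.2 ± 5.26 CPM. Mir302d, from a cluster active in pluripotent cells, had 5.36 ± 0.0398 CPM, and the pluripotency list took 0.00117% in each library. The neural list had 2 counts in each library over its 6 genes, below the limit of 3 counts, and its best gene, Mir9-3, had 1 count in replicate 1 and 2 in replicate 2. All 6 neural hairpins share at least 20 bases with another counted hairpin, so reads of their mature forms could have been left out.

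**Figure D3:**
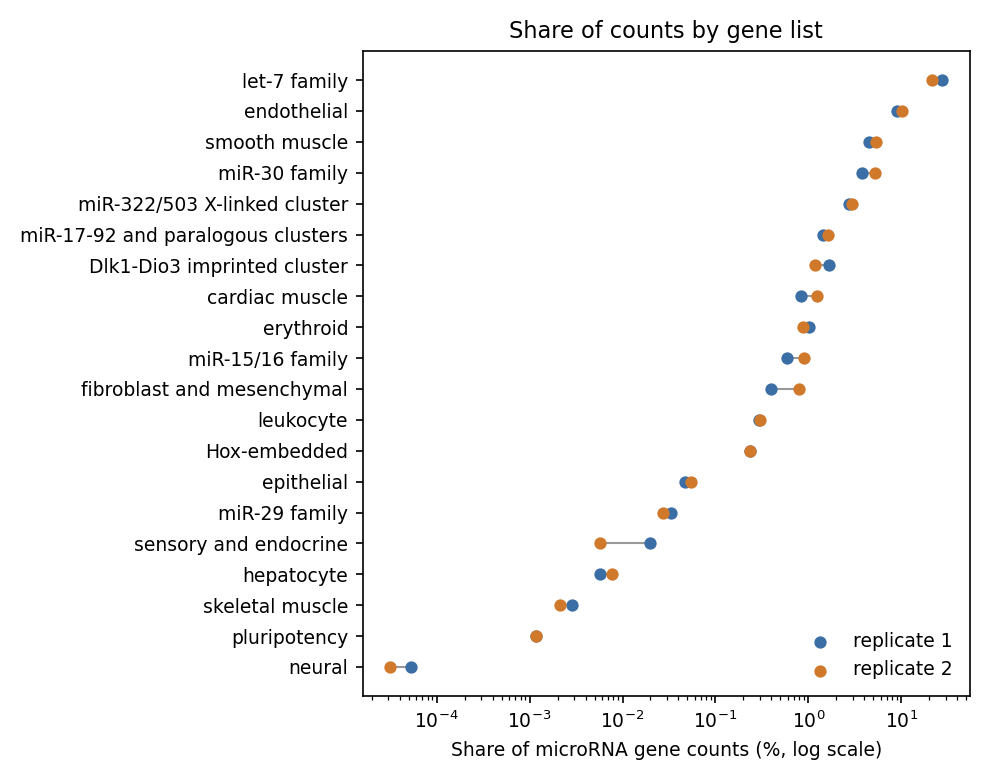
Points give the share of all microRNA gene counts, in percent on a log scale, taken by each of the 20 gene lists in replicate 1 and replicate 2, and the grey lines join the 2 values of a list. The let-7 family lies highest at 27.5% and 21.5%, the neural list lies lowest, and the sensory and endocrine list shows a wide gap, from 0.0197% to 0.00577%.

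Across the 340 detected genes the replicates had a Pearson correlation of 0.971 and a Spearman correlation of 0.965 on the log2(CPM + 1) scale. Genes are not independent replicates, so no p-value belongs to these values. The SD of the log2 ratio between the libraries was 0.92, and the median absolute log2 ratio was 0.54. The biological coefficient of variation was 0.415 from the common dispersion of edgeR and 0.236 from the median genewise dispersion of DESeq2. Against counting error alone, 245 genes (72.1%) differed between the libraries by an exact binomial test with Benjamini-Hochberg adjustment at 0.05. Of these, 116 were higher and 129 lower in replicate 2, and 67 differed by at least 2-fold. The larger side depended on the scaling, with 97 higher and 146 lower under total counts and 124 higher and 113 lower under DESeq2 size factors. A chi-square statistic of 978 per degree of freedom over the detected genes shows that the files do not hold 1 library deposited as both. This test compares 2 libraries and not conditions. The scaling sets the zero of these ratios, and the TMM factors used here moved all log2 ratios by 0.14 against total counts.

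Mir301 and Mir31 differed most between the libraries among called genes with a mean of at least 10 CPM. Mir301, in an intron of Ska2 (chromosome 11, 87113004 to 87113089, plus strand), had 223 CPM in replicate 1 and 2977 CPM in replicate 2 and was 14.7-fold higher after TMM scaling. Its log2 ratio was 3.88 (exact 95% interval 3.78 to 3.98). Mir148a was 6.82-fold higher, Mir101a 6.34-fold, Mir195a 5.88-fold and Mir301b 5.88-fold. In the other direction Mir31 had 375 and 29.3 CPM and was 11.5-fold lower in replicate 2 after TMM scaling (log2 ratio -3.53, interval -3.76 to -3.31). Mir543 was 6.90-fold lower, Gm23935 6.604-fold, Mir193a 4.96-fold and Mir298 4.57-fold. Gm23935 shares at least 20 bases with 5 other counted hairpins and Mir101a with 1, and both are uncertain for that reason.

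Of the 15 lists with at least 3 detected genes, 3 had a median log2 ratio outside the central 95% of 10000 random lists matched on mean level. The cardiac muscle list had a median of 0.98 toward replicate 2, at percentile 99.8 of its random lists. Mir208a ran against it, and Mir1a-1, which did not pass the test, had a log2 ratio of -0.08. With 6 detected genes, that median lies midway between Mir499 (log2 ratio 1.18) and Mir133a-1 (0.78). Mir133a-1 did not pass the test, had only 10 and 27 counts and shares sequence with other hairpins, so the median is uncertain. The leukocyte list had a median of 0.92, at percentile 99.2, although its most abundant genes, Mir155 and Mir146, ran against it and the log2 ratio of its summed counts was 0.19. The sensory and endocrine list had a median of -1.64, at percentile 1.02, and all 3 of its detected genes were lower in replicate 2 under each of the 3 scalings. Let-7 had a median of -0.25, at percentile 8.87, and the fibroblast and mesenchymal list one of 0.78, at percentile 94.95, both inside the range. The random lists treat genes as independent, whereas Mir182 and Mir183 lie in 1 genomic cluster, as do Mir1a-2 and Mir133a-1, so the lists hold fewer separate loci than genes. These percentiles describe the 2 libraries and are not p-values.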

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

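Of the tests in this part, the one on low yield was chosen after the result was seen. The multi-mapping reads and the opposite-strand column lie outside the comparisons of the report. Each exceeded the limit that a count of 0 allows, and no control samples exist in the series analysed here to set beside them. Reads with several mapping positions were 36.8% of all reads in replicate 1 and 48.1% in replicate 2, or 0.868 and 1.30 reads per read assigned to a gene. The column for the opposite strand held 61 counts in replicate 1 and 114 in replicate 2 in genes with no overlapping counted gene, which is 0.00221% and 0.00250% of the counts on the gene strand of the same genes.

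Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2 together held few counts for heart tissue, and a low yield of heart muscle microRNAs as a whole is argued against by Mir499, which had at least 3678 CPM in each library. A candidate explanation is that reads of mature sequences encoded in several copies were left among the multi-mapping reads. All 4 hairpins share at least 20 bases with another counted hairpin, and over 5 family lists the 17 genes that share such a stretch had a median log2(CPM + 1) below that of the 26 that do not (difference -2.60, 261 against 1602 CPM, permutation p = 0.0131, two-sided). These genes are not independent, since they fall into 5 lists and some lie in 1 genomic cluster, so this p-value may be too small. A shared stretch does not by itself remove the counts, since genes with one held 25.7% of all counts, Mir378a, Mir23b and Mir23a among them. Mature sequences were not compared here, so those genes may share less of theirs than the 4 heart muscle genes do. The candidate explanation therefore stays a hypothesis. No biological explanation was tested, and the multi-mapping reads were not assigned to sequences here.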

How the results depend on the processing

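All alternatives in this part were fixed before the data were examined. No paired analysis was possible because the series analysed here has 1 group. Counting both strands dropped genes that overlap a gene on the other strand, so the leading gene fell to 0% and the endothelial and erythroid lists to 0.0833% and 0.0529%, while the smaller total raised let-7 to 32.4%, smooth muscle to 6.73%, cardiac muscle to 1.42% and leukocyte to 0.385%. A total without the leading gene gave 11.1% for endothelial, 5.69% for smooth muscle, 1.11% for erythroid and 0.347% for leukocyte, and 61.4% for the 10 leading genes. A minimum of 1 count gave 574 detected genes and one of 100 counts gave 216. The replicate correlation was 0.988 with no filter and 0.960 without the 20 leading genes. Of the 2202 genes, 1469 had no count in either library and so were equal in both. Such genes can raise a correlation with no filter, so the 0.988 is not closer agreement of the replicates. The median genewise dispersion of DESeq2 gave a coefficient of variation of 0.236, against 0.415 from edgeR. A 2-fold criterion left 67 of the 245 differing genes. The leukocyte shift fell to 0.19 as the log2 ratio of summed counts, in which its abundant genes Mir155 and Mir146 weigh most. With total counts the log2 ratios of Mir378a (-0.0095), Mirlet7g (-0.12) and Mir139 (-0.0790) reversed, and with DESeq2 size factors those of Mir99a (0.0436) and Mir451a (0.00293) did. These scalings moved every ratio alike, by 0.14 and 0.08, which is more than these genes differed. Leaving out a replicate leaves the value of the other library, which for a share or a ratio says nothing about stability. Depth limited low genes most, with 10 and 27 counts behind the ratio of Mir133a-1.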

Other observations

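Of the tests in this part, those on counting error for the Mir208 pair and all those on numbered families were chosen after the result was seen. Among genomic clusters, which were picked out here by their share of the counts, that of Mir99a and Mirlet7c-1 on chromosome 16 took 5.15% ± 0.449 (SD, n = 2) of the counts, and that of Mir23b, Mir27b and Mir24-1 on chromosome 13 took 5.10% ± 0.533. Genes of 1 cluster differed widely in count, with Mir99a at 51092 CPM and Mirlet7c-1, which shares at least 20 bases with 2 other counted hairpins and is uncertain for that reason, at 435 CPM. The imprinted region of chromosome 12 held a cluster led by Mir379 with 33 detected genes between 109709060 and 109747960, which took 0.921% ± 0.129, and another led by Mir127 with 11 detected genes, which took 0.493% ± 0.208. The X chromosome had 33 detected genes with 5.41% ± 0.230 of the counts.

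Most detected genes differed between the 2 libraries by more than counting error. Low depth is argued against as the cause, since the SD of the log2 ratio was still 0.80 over the 116 genes with at least 1000 counts in both. Hairpin GC content accounts for little of the spread, because removing its linear trend left 0.964 of the SD. The Pearson correlation of the log2 ratio with GC content was -0.266 across genes, which are not independent replicates. Differences between the animals and between the library preparations stay open as candidate explanations, and with 1 library per animal they could not be separated.

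Of 37 families of related genes at separate loci, 26 had all genes on the same side of 0 and 11 had genes on both sides, as had Mir24, Mir15 and Mir199. Neighbouring genes on the same strand at most 10 kb apart were taken as 1 cluster. Loci further apart counted as separate, also where they lie near each other, as those of the Mir467 and Mir669 families on chromosome 2 do. The count on the same side was 26 with DESeq2 size factors, 24 with total counts and 17.6 on average with the ratios permuted over genes. Mir301 and Mir301b, on chromosomes 11 and 16, had log2 ratios of 3.88 and 2.55, Mir101a and Mir101b had 2.67 and 1.79, and Mir34a and Mir34c had -1.26 and -1.66. The Mir301 pair prompted a test over families of the same number, with 1 gene kept per genomic cluster within each family. Without that pair, the intraclass correlation of the log2 ratio within 36 families was 0.446 (permutation p = 0.0004, adjusted 0.0008 over 2 such tests), and with it 0.535. Over the 18 families whose genes share no stretch of 20 bases, again without that pair, it was 0.388 (permutation p = 0.0191, not adjusted). Within clusters of neighbouring genes it was 0.197 (permutation p = 0.0121, adjusted 0.0121). Some clusters gave genes to several families, as that of Mir23b, Mir27b and Mir24-1 did. Mir130b, which stayed in when the Mir301 pair was left out, lies in 1 cluster with Mir301b. The families are therefore not all independent, and their permutation p-values may be too small. Bootstrap 95% intervals were 0.188 to 0.732 for all families, the Mir301 pair included, and 0.00197 to 0.448 for clusters, and the interval of their difference, -0.0669 to 0.621, includes 0. A hypothesis is that part of the difference between the libraries may follow mature sequence, as a bias in library preparation or a family-wide change in the tissue would, and not only the transcript of origin. The value fell short of the 0.5 set as needed for that hypothesis, so the question stays open, as it does for clusters.

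The Mir208 pair parted further than any other of the 37 families, by 3.59 on the log2 scale, ahead of the Mir24 family at 2.88. Counting error is argued against by a gap of 53.3 percentage points between the exact 95% intervals of the Mir208a share in the 2 libraries. Removing the linear GC trend left a difference of 3.49. The hairpins of Mir208a and Mir208b are close in GC content, at 49.4% and 45.5%. The test on GC content therefore had little room to come out otherwise, and no conclusion is drawn from it. The general spread between the libraries cannot be told apart from a change specific to this pair, since 2.06% of the 4278 pairs of detected genes of like abundance were at least as far apart. A difference between the animals in the balance of the host genes Myh6 and Myh7 may be worth following up, but no biological explanation was tested, because the series analysed here holds 1 group and no messenger RNA was analysed here.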
